A study of Mus musculus with 27 samples.

How the data were processed

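The deposited tables held counts per gene and library as made by the authors, and these counts were the sole input to every test. Reads were handled with CASAVA 1.8.2, cutadapt, STAR 2.4.2a and DESeq2, on the mm10 build, per the submitters' processing notes. The counter, the gene annotation and any deduplication are not given in the sources used here. The deposited tables list only genes that reached 6 counts in at least 1 library, so weaker genes are absent.

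Other deposited columns served only for checks. The normalized signal values deposited by the authors equal the count divided by 1 size factor per sample. The deposited log2 values are the authors' regularized logarithms, batch-adjusted logarithms and fold changes, the last as wild type over knockout in the Ythdf stem cell comparisons. The deposited p-values are the authors' DESeq2 results, and a mean of normalized counts (other) stands beside them. Every per-sample column was matched to a sample by the sample labels, and 0 were left over. In the post-GV set the title of 1 heterozygous library repeats replicate 2 where its bracketed name gives 3, and it was taken as replicate 3.

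The 27 libraries form 12 groups, and 10 comparisons were set in the design. Each experiment was fitted alone in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr on groups, robust quasi-likelihood F test) and limma 3.58.1, with DESeq2 1.42.0 as the alternative. Stem cell contrasts came from 1 fit to 12 libraries, with 11951 of 14006 genes kept; 13551 of 16598 were kept for GV oocytes, 13910 of 16304 for post-GV oocytes and 16031 of 17715 for spermatids. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes. Levels are CPM after TMM scaling. Where a group had 0 counts, the fold was bounded from a floor of 3 counts over that group. Standard errors and floors cover counting error and replicate spread alone, not differences between cultures or animals beyond the sampled ones. The motif test is an exception, with errors from resampling genes.

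A set of 30 gene lists was fixed beforehand, and those with at least 3 tested members were tested by camera with a preset correlation of 0.01 between genes, beside an estimated correlation and fry, adjusted over the lists of each comparison. Counts adjusted over a list alone are given where they differ from the calls. Mitochondrially encoded mRNAs had too few tested members and gave no result. Genes named in each comparison are Ythdf1, Ythdf2, Ythdf3 and Mettl3, the 8 largest called rises and 8 largest called falls with a mean log2 CPM of at least 4 and every knockout library on the same side of every control, and up to 4 members per list with the smallest p. Predicted and clone symbols, ribosomal pseudogenes, mitochondrial and Y-linked genes and Xist were left out of the largest rises and falls, and the contrast beyond the sum took 5 each way without the library condition. From these, examples were picked for the text. Gene positions and transcript features came from GENCODE M21 (GRCm38), where 96.2%, 96.3%, 96.3% and 96.0% of symbols in the stem cell, GV, post-GV and spermatid tables were found.

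Alternatives fixed before the data were examined were RLE scaling, no expression filter, a stricter filter of 5 CPM (in stem cells it kept more genes, 13796), a fit on the compared groups only, DESeq2, replicate number as a block and leaving out each library in turn. A batch term and a fit to the first batch for post-GV oocytes, and a fit without GV controls 2 and 3, were added after the data were seen. Shared numbers of GV replicates were tested for pairing by correlating residuals: 0.623, 0.115 and 0.387 for numbers 1 to 3, so the numbers were taken as paired in the block fit, though 2 of 9 pairs with different numbers also passed 0.1. By contrast stem cell libraries with the same letter correlated at 0.00112 to 0.152, all above 0, and those with different letters at the mirror values, as each group has 2 libraries. Of these, the Ythdf1 with the Ythdf2 knockout was the only pair of groups past 0.1. Post-GV pairs gave 0.562 and -0.701. Fold changes of unchanged groups sharing controls were simulated in 20 draws.

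What each fit can find was measured on simulated counts with 200 genes changed by construction, 100 by 2-fold and 100 by 4-fold. The counts were drawn for each gene separately from the pooled means and fitted spread of each experiment. Only genes with a mean log2 CPM of at least 4 were changed. Effects that many genes share within a library are absent from such counts, so the numbers found and falsely called leave them out. edgeR found 82 and 98 with 12 false calls in the triple knockout layout, 11 and 89 with 4 in GV oocytes, 0 and 0 with 0 in post-GV oocytes, 8 and 63 with 9 there with the batch term, and 39 and 95 with 19 in spermatids. DESeq2 found 55 and 90 with 0, 33 and 98 with 33, 1 and 20 with 43, 21 and 84 with 25, and 35 and 95 with 13. The authors' deposited adjusted values under 0.05 number 125, 70, 74, 673 and 1137 for the Ythdf1, Ythdf2, Ythdf3, triple and Mettl3 stem cells, 212 for GV oocytes, 649 for post-GV oocytes and 350 for spermatids. Benjamini-Hochberg adjustment of the deposited p-values gives 5208 for GV oocytes, and 51, 10 and 25 for Ythdf1, Ythdf2 and Ythdf3, so these deposited adjusted values are not that adjustment. It gives the deposited number in the other comparisons.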

Results

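RNA was sequenced from mouse cells that had lost readers or the writer of N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA. Embryonic stem cells of the KH2 line gave 12 poly(A) libraries in 6 groups of 2: wild type, single knockouts of Ythdf1, Ythdf2 and Ythdf3, a knockout of all 3 readers (triple knockout) and a Mettl3 knockout. Germinal vesicle (GV) oocytes gave 7 SMART-seq2 libraries. They were 3 from Mettl3-floxed females with the oocyte-active Zp3-Cre transgene and 4 from Cre-negative controls. Oocytes past the GV stage gave 5 SMART-seq2 libraries, 2 Ythdf2 knockout and 3 heterozygous. Sorted round spermatids gave 3 Ribo-Zero libraries, 2 Ythdf2 knockout and 1 wild type. Assigned counts per library ran from 612598 to 1111764 in stem cells, 6484397 to 18181397 in GV oocytes, 12409822 to 25015081 in post-GV oocytes and 18843689 to 32759740 in spermatids.

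The single knockouts ask which mRNAs depend on 1 reader alone, and the triple knockout asks which depend on the readers jointly. A contrast of the triple against the sum of the singles looks for effects that do not add. The Mettl3 lines ask what loss of the mark itself does in stem cells and in growing oocytes. The Ythdf2 oocytes and spermatids ask what loss of that reader does in the female and male germ line. Comparisons, lists and the rule for naming genes were chosen before the data were examined, except where a sentence says otherwise. Fold changes are log2 ± standard error. Levels are mean ± standard deviation in CPM (counts per library scaled to a common total). A gene is "called" at an adjusted p under 0.05 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment over all tested genes. The p-values measure only the spread between samples, since the labels do not say whether stem cell replicates came from separate cultures or lines. The oocyte protocol speaks of oocytes collected per mouse. Stem cell replicates differed by less than Poisson counting error (chi-square per gene 0.675 to 0.832 in 6 of 6 pairs), so their p-values may be too small for separately grown cells. Of 60 stem cell pairs from different groups 8 were also under 1, the lowest at 0.842. Members of the Usp17l, Zscan4, Tcstv and Pramel families are near-identical copies, so their single-gene values are uncertain. Lists that hold such copies count each as a separate gene. Their gene counts and list p-values thus rest on fewer independent genes than the number tested, and those p-values may be too small.

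In Ythdf1 knockout stem cells the Ythdf1 transcript, which encodes a cytoplasmic m6A reader (chromosome 2, 180904377 to 180920949, minus strand, GRCm38) stood at 174 ± 1.88 against 174 ± 4.39 CPM, a log2 change of -0.00 ± 0.09, adjusted p = 0.995 (2 libraries each). An unreduced count over the whole gene checks nothing, because the labels do not give the deleted part. The same holds for every Ythdf knockout here. Ythdf2 (0.32 ± 0.23, adjusted p = 0.640), Ythdf3 (-0.00 ± 0.22, adjusted p = 0.999) and Mettl3, the m6A methyltransferase (-0.10 ± 0.10, adjusted p = 0.783), were not called.

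Among named genes the largest rises were mostly of the 2-cell embryo programme. Tcstv3, transcribed at the 2-cell stage, rose by 4.56 ± 0.47, 23.7-fold, adjusted p = 7.33e-12 (34.9 ± 10.4 against 1.33 ± 0.618 CPM, 2 libraries each). Usp17lb, a deubiquitinase-like member of a repeated family, rose by 3.72 ± 0.20, 13.1-fold (118 ± 3.66 against 8.88 ± 1.32 CPM). Dppa3, a maternal factor that protects DNA methylation, rose by 1.85 ± 0.15, adjusted p = 1.08e-16, and Fbxo15, an F-box gene marking undifferentiated cells, rose by 0.95 ± 0.07, adjusted p = 2.12e-17. Slc15a2, a peptide transporter (-2.54 ± 0.36), Foxd1, a forkhead factor (-2.22 ± 0.30), Zmat4, a zinc-finger gene of little-studied function (-2.01 ± 0.28), and Cdx2, a trophoblast factor (-2.74 ± 0.50), fell.

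Of 11951 tested genes 412 were called, 233 up and 179 down, with 109 and 81 past 2-fold. All 21 tested 2-cell stage genes rose (21 adjusted over the list alone, median log2 change 3.31, or 3.28 with the floor for 1 gene absent in wild type, list adjusted p = 2.68e-92, and adjusted p = 2.85e-05 with an estimated correlation). Near-identical copies in this list were counted as separate genes here and in every other comparison, so the 21 are not independent. Germline genes rose in 4 of 15 (6 adjusted over the list alone, median 0.32, list adjusted p = 8.05e-06, adjusted p = 0.0413 with an estimated correlation). They include Dpep3, a meiosis-linked dipeptidase (1.25 ± 0.19), Ddx4, the germ-cell helicase (1.12 ± 0.23), Dazl, a germ-cell translation factor (0.57 ± 0.11), and Mael, a piRNA-pathway gene (0.78 ± 0.20). The p53 targets moved up as a list (2 of 17 rose, 3 adjusted over the list alone, median 0.20, adjusted p = 0.00049, adjusted p = 0.0413 with an estimated correlation). Pmaip1, a death-promoting BH3 gene (0.68 ± 0.13), and the kinase gene Plk2 (0.44 ± 0.11) rose. Naive pluripotency genes gave 6 rises and 1 fall of 26 (8 and 4 adjusted over the list alone, median 0.10, adjusted p = 0.00049, lost at adjusted p = 0.121 with an estimated correlation). Nanog rose (0.30 ± 0.07) and Klf5, a Krüppel-like factor, fell (-0.22 ± 0.05). Ribosomal protein genes shifted slightly up (2 rose and 1 fell of 73, 2 and 2 adjusted over the list alone, median 0.07, adjusted p = 0.0087, lost at adjusted p = 0.529 with an estimated correlation and also without wild-type library A).

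No call was made among the m6A writer complex, m6A readers and erasers, CCR4-NOT deadenylase, decapping or interferon-stimulated lists. Formative genes gave 0 rises and 3 falls of 14 (2 and 4 adjusted over the list alone). These were Lefty2, a Nodal antagonist (-0.55 ± 0.10), Lefty1, its neighbour (-0.86 ± 0.22), and Zic2, a zinc-finger factor (-0.37 ± 0.10). Immediate-early genes fell in 2 of 14, Myc, the growth regulator (-1.54 ± 0.27), and Ier3, a stress-response gene (-1.12 ± 0.31). ATF4 targets had 1 fall of 16 (2 over the list alone), the neural list 1 of 9 (Ncam1, a cell adhesion gene, -1.56 ± 0.44) and the trophoblast list 1 of 8 (Cdx2, 2 over the list alone). Mesoderm and endoderm genes held none (3 falls over the list alone). A gene rose in each of the primitive endoderm (2 rises and 2 falls over the list alone) and fibroblast feeder lists (for the latter Thy1, a surface marker, 1.98 ± 0.41). None of these lists was called as a whole, and median and mean differed in sign for readers and erasers, mesoderm and endoderm, primitive endoderm and trophoblast. DESeq2 called 56 genes here (52 up, 4 down), and of the genes given values above it kept Tcstv3, Usp17lb, Dppa3, Fbxo15, Slc15a2 and Foxd1 alone. The edgeR count was 221 without wild-type library A, 240 without B, 222 without knockout library A and 192 without B.

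In Ythdf2 knockout stem cells the Ythdf2 transcript, of the reader tied to mRNA decay (chromosome 4, 132184912 to 132212303, minus strand) stood at 14.1 ± 5.34 against 25.3 ± 0.809 CPM, and its change of -0.85 ± 0.29 was not called (adjusted p = 0.216). Ythdf1 (0.01 ± 0.09), Ythdf3 (0.12 ± 0.22) and Mettl3 (-0.11 ± 0.10) were not called.

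Mest, an imprinted hydrolase-like gene active on the paternal copy, rose most among the named genes (4.68 ± 0.31, 25.7-fold, adjusted p = 9.46e-20, 72.1 ± 2.38 against 2.66 ± 0.0192 CPM, 2 libraries each). Pdzrn4, a PDZ and RING domain gene (2.24 ± 0.42), Lcp1, an actin-bundling protein of blood cells (1.39 ± 0.28), and Dppa3 (1.02 ± 0.17) rose too. Zmat4 (-2.16 ± 0.29), Lefty1 (-1.70 ± 0.27), Apol6, an apolipoprotein L gene (-1.67 ± 0.28), and Agps, an ether-lipid synthase of peroxisomes (-1.65 ± 0.33), fell.

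Calls numbered 227, 100 up and 127 down, with 20 and 45 past 2-fold. Among 21 2-cell stage genes 1 rose, Usp17lc (1.35 ± 0.28), and 5 adjusted over the list alone. The median was 0.90 with 19 of 21 positive (list adjusted p = 2.62e-06, lost at adjusted p = 0.0701 with an estimated correlation). Naive pluripotency genes rose in 4 of 26 (7 rises and 1 fall adjusted over the list alone, median 0.06, adjusted p = 0.0137, lost at adjusted p = 0.202 with an estimated correlation). Fbxo15 (0.56 ± 0.08), Tdh, a threonine dehydrogenase (0.31 ± 0.06), and Dppa5a, a pluripotency-associated KH gene (0.28 ± 0.06), rose. Formative genes gave 1 rise and 3 falls of 14 (1 and 4 adjusted over the list alone, median -0.19, adjusted p = 0.0429, lost at adjusted p = 0.202 with an estimated correlation). Otx2, a homeobox factor, rose (0.94 ± 0.22) as Lefty2 (-0.68 ± 0.10), Lefty1 and Zic2 (-0.54 ± 0.11) fell. Interferon-stimulated genes had 1 fall of 10, the nucleic acid sensor Zbp1 (-0.84 ± 0.20, median -0.30, adjusted p = 0.0429, lost at adjusted p = 0.202 with an estimated correlation). Ribosomal protein genes had 1 rise and 1 fall of 73 (median 0.05, adjusted p = 0.0429, lost at adjusted p = 0.632 with an estimated correlation).

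Myc (-1.11 ± 0.26), Cdx2 (-1.78 ± 0.44), Ncam1 (-1.91 ± 0.48) and Col1a1, a fibroblast collagen (-1.08 ± 0.22), were the lone calls of the immediate-early, trophoblast, neural and feeder lists. No gene of the p53, ATF4, germline, mesoderm and endoderm, primitive endoderm, writer, reader, deadenylase or decapping lists was called, though 1 germline gene rose, and 1 mesoderm and endoderm gene rose and 1 fell, adjusted over the list alone. Trophoblast genes gave 1 rise and 1 fall in that way. Median and mean or test differed in sign for writers, readers and erasers, ATF4 targets, immediate-early genes, primitive endoderm and trophoblast. DESeq2 called 11 genes, of those given values above Mest and Fbxo15 alone. There edgeR called 103 without wild-type library A, 122 without B, 104 without knockout library A and 54 without B. As lists, ribosomal protein genes lost their call without wild-type A or knockout B, formative genes without wild-type A or either knockout library, interferon genes without wild-type B or knockout A, and naive genes without knockout A.

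In Ythdf3 knockout stem cells the Ythdf3 transcript, of the remaining cytoplasmic reader (chromosome 3, 16183212 to 16217037, plus strand) stood at 76.1 ± 7.15 against 68.8 ± 4.89 CPM (0.14 ± 0.23, adjusted p = 0.867). Ythdf1 (-0.22 ± 0.10), Ythdf2 (0.53 ± 0.24) and Mettl3 (0.00 ± 0.10) were not called.

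The 2-cell stage genes were again up. Tcstv1 rose by 2.72 ± 0.39, 6.59-fold (27.2 ± 1.30 against 3.99 ± 0.656 CPM, 2 libraries each). Usp17lb rose by 2.63 ± 0.26, adjusted p = 2.84e-11 and Zscan4d, a telomere-linked zinc-finger gene, by 2.43 ± 0.31. Zmat4 (-2.96 ± 0.36), Mal, a myelin and lymphocyte proteolipid (-2.50 ± 0.52), Foxd1 (-2.21 ± 0.33), Bmp4, a growth factor of early patterning (-1.97 ± 0.33), and Zbp1 (-1.65 ± 0.24) fell.

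The comparison called 340 genes, 208 up and 132 down, with 68 past 2-fold each way. Rises took in 17 of 21 2-cell stage genes (20 adjusted over the list alone, median 2.20, list adjusted p = 9.48e-42, adjusted p = 0.000345 with an estimated correlation). Germline genes rose in 3 of 15 (4 adjusted over the list alone, 14 positive, median 0.47, adjusted p = 4.88e-06, lost at adjusted p = 0.0573 with an estimated correlation). Hormad1, a meiotic chromosome-axis gene (0.81 ± 0.13), Dpep3 (1.16 ± 0.21) and Dazl (0.55 ± 0.12) were those called. Naive pluripotency genes rose in 4 of 26 (8 rises and 2 falls adjusted over the list alone, median 0.11, adjusted p = 3.85e-05, lost at adjusted p = 0.0607 with an estimated correlation). Fbxo15 (0.76 ± 0.08), Nanog (0.52 ± 0.07) and Sox2, a core pluripotency factor (0.32 ± 0.07), rose. Of 17 p53 targets 2 rose, Pmaip1 (0.78 ± 0.14) and Gtse1, a G2-phase p53 regulator (0.37 ± 0.09). With 3 adjusted over the list alone, the list leaned up (median 0.20, adjusted p = 0.00382, lost at adjusted p = 0.0607 with an estimated correlation). Ribosomal protein genes rose in 4 of 73 (8 rises and 1 fall adjusted over the list alone, median 0.08, adjusted p = 0.000256, lost at adjusted p = 0.284 with an estimated correlation).

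ATF4 targets gave 2 rises, Ddit4, an mTOR inhibitor (0.63 ± 0.12), and Asns, asparagine synthetase (0.25 ± 0.06), and 1 fall, Phgdh, the first enzyme of serine synthesis (-0.63 ± 0.17). Single falls came from the interferon (Zbp1, 2 over the list alone), mesoderm and endoderm (Cxcr4, a chemokine receptor, -1.60 ± 0.37), neural (Map2, a microtubule gene of neurons, -2.26 ± 0.63, 2 over the list alone) and trophoblast (Cdx2, -1.86 ± 0.48) lists, and 1 rise from primitive endoderm (Sparc, a matrix protein, 0.32 ± 0.07, with 1 fall too over the list alone). The writer, reader, deadenylase, decapping, immediate-early, formative and feeder lists held 0 calls. Median and mean or test differed in sign for writers, decapping, ATF4 targets and trophoblast. DESeq2 called 29 genes (26 up, 3 down), keeping Tcstv1, Usp17lb, Zscan4d, Zmat4, Fbxo15 and Nanog of those given values above. The edgeR count was 149 without wild-type library A, 199 without B, 125 without knockout library A and 112 without B.

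In the triple knockout the transcripts of the targeted genes were not called. Ythdf1 stood at 159 ± 0.611 against 174 ± 4.39 CPM, 2 libraries each (-0.13 ± 0.10, adjusted p = 0.471), Ythdf2 32.7 ± 4.03 against 25.3 ± 0.809 CPM (0.36 ± 0.24, adjusted p = 0.383) and Ythdf3 72.1 ± 13.8 against 68.8 ± 4.89 CPM (0.06 ± 0.23, adjusted p = 0.898). Mettl3 was not called either (-0.11 ± 0.11). Pramel7, an oocyte and embryo gene of a repeated family, rose by 5.66 ± 0.33, 50.7-fold, adjusted p = 4.67e-24 (97.6 ± 3.89 against 1.77 ± 1.24 CPM, 2 libraries each). Sp110, an interferon-linked nuclear body gene, rose by 4.71 ± 0.38, 26.3-fold, Usp17lb by 4.63 ± 0.18, 24.7-fold and Zscan4d by 4.28 ± 0.22. Zmat4 fell furthest among the named genes (-5.74 ± 0.55), followed by Zbp1 (-3.94 ± 0.36, adjusted p = 9.48e-15, 3.67 ± 1.36 against 57.7 ± 3.35 CPM). Also lower were Aldh1a3, a retinoic acid synthesis enzyme (-3.35 ± 0.55), and the homeobox gene Nkx6-3 (-3.30 ± 0.34).

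Of the tested genes 25.1% were called, 2997 in number (1588 up, 1409 down, 534 and 607 past 2-fold). Each of the 21 2-cell stage genes rose (21 adjusted over the list alone, median 4.11, list adjusted p = 1.69e-58, adjusted p = 0.000265 with an estimated correlation). Germline genes rose in 11 of 15 (12 adjusted over the list alone, median 1.29, adjusted p = 8.39e-10, adjusted p = 0.0166 with an estimated correlation). Rises took in Dazl (1.52 ± 0.10), Sycp1, a synaptonemal complex protein (1.47 ± 0.17), Asz1, a piRNA-pathway scaffold (3.37 ± 0.47), and Hormad1 (1.18 ± 0.13). Interferon-stimulated genes fell in 4 of 10 (1 rise and 4 falls adjusted over the list alone, median -0.48, adjusted p = 0.00624, lost at adjusted p = 0.0844 with an estimated correlation). The falls were Zbp1, the RNA sensor Ddx58 (-2.67 ± 0.40), the RNA-activated kinase Eif2ak2 (-1.53 ± 0.23) and the antiviral membrane gene Ifitm3 (-0.50 ± 0.10).

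Some lists split. Naive pluripotency genes rose in 9 and fell in 7 of 26 (9 and 8 adjusted over the list alone, median 0.02). Those up include Fbxo15 (1.59 ± 0.07), Dppa3 (2.10 ± 0.15) and Nanog (0.71 ± 0.07), and Klf5 fell (-0.72 ± 0.06). Ribosomal protein genes rose in 10 and fell in 6 of 73. The p53 targets rose in 6 and fell in 1 of 17 (median 0.27), led by Pmaip1 (1.17 ± 0.13). Trophoblast genes rose in 4 and fell in 2 of 8, Esx1, a placental homeobox gene (2.54 ± 0.38), against Cdx2 (-2.35 ± 0.52). Neural genes split 2 and 2 of 9 (2 and 3 adjusted over the list alone) and formative 2 and 2 of 14. Mesoderm and endoderm gave 1 rise and 3 falls of 7 (Gsc, an organizer homeobox gene, 1.61 ± 0.27, T, the mesoderm factor, -1.78 ± 0.40), ATF4 targets 1 and 2 of 16, and immediate-early genes 1 and 2 of 14. Median and mean or test differed in sign for readers and erasers, decapping, formative genes and primitive endoderm. The deadenylase list fell in 2 of 18, the scaffold Cnot1 (-0.88 ± 0.20) and Cnot11 (-0.62 ± 0.15). Decapping fell in 1 of 16 (Lsm5, -0.53 ± 0.16, 0 over the list alone), readers and erasers in 1 of 14 (Igf2bp3, an mRNA-stabilizing reader, -0.46 ± 0.12) and primitive endoderm in 1 of 6 (Lama1, a laminin, -1.58 ± 0.19). Thy1 (2.12 ± 0.43) rose among feeder genes and the writer complex held 0 calls. As a whole, none of these lists was called by camera. By fry, p53 targets (adjusted p = 0.000661), feeder (0.00281), naive pluripotency (0.00521) and trophoblast genes (0.00521) passed 0.05, and the rest of these lists did not. DESeq2 called 785 genes (472 up, 313 down), without Ifitm3, Cdx2, T, Cnot1, Cnot11, Lsm5 and Igf2bp3. With edgeR the count was 1809 without triple knockout library A and 1796 without B.

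Mettl3 knockout stem cells lost most of the Mettl3 transcript, which encodes the m6A methyltransferase (chromosome 14, 52294841 to 52305128, minus strand). It stood at 16.5 ± 1.99 against 138 ± 2.24 CPM (-3.07 ± 0.18, adjusted p = 1.11e-23). Ythdf2 rose by 1.30 ± 0.20, adjusted p = 9.74e-07 (62.2 ± 0.587 against 25.3 ± 0.809 CPM), while Ythdf1 (0.22 ± 0.09, adjusted p = 0.121) and Ythdf3 (0.26 ± 0.22, adjusted p = 0.405) were not called. Mest rose again (4.68 ± 0.32, 25.6-fold), as did Atp10a, a phospholipid flippase (4.64 ± 0.37). Grin1, an NMDA receptor subunit (3.99 ± 0.25, 105 ± 26.8 against 6.66 ± 1.93 CPM, 2 libraries each), rose too. Adcy2, an adenylate cyclase, Aldh1a3 and the homeobox gene Hoxa5 had 0 counts in the knockout, at least 15.5-fold, 11.6-fold and 10.5-fold lower than wild-type levels of 31.5, 23.5 and 21.3 CPM. Zmat4 (-5.82 ± 0.55), the ETS factor Etv1 (-5.24 ± 0.60) and the homeobox gene Tlx2 (-4.72 ± 0.34) fell.

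In all 3629 genes (30.4% of those tested) were called, 1820 up and 1809 down, with 504 and 872 past 2-fold. ATF4 targets rose in 8 of 16 (8 adjusted over the list alone, median 0.29, list adjusted p = 0.00581, lost at adjusted p = 0.234 with an estimated correlation). They include Trib3, a stress pseudokinase (1.36 ± 0.13), Chac1, a glutathione-degrading enzyme (2.03 ± 0.20), and Psat1, of serine synthesis (0.49 ± 0.08). The p53 targets went the other way, 1 up and 10 down of 17 (2 and 10 adjusted over the list alone, median -0.46, adjusted p = 0.0112, lost at adjusted p = 0.234 with an estimated correlation and also without knockout library B). Falls took in Ccng1, a cyclin-like p53 target (-0.88 ± 0.11), the receptor gene Eda2r (-0.995 ± 0.12), Aen, an exonuclease of cell death (-1.95 ± 0.34), and Phlda3, an AKT inhibitor (-0.75 ± 0.14).

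No other list was called as a whole by camera. By fry, primitive endoderm (adjusted p = 0.0021), neural (0.00318), reader and eraser (0.0118), mesoderm and endoderm (0.0118) and writer (0.0307) lists passed 0.05, and the rest did not. The writer complex gave 3 rises and 1 fall of 9. The partners Wtap (1.14 ± 0.09, adjusted p = 6.76e-18, 317 ± 36.8 against 142 ± 0.863 CPM), Rbm15 (1.11 ± 0.11) and Zc3h13 (0.41 ± 0.13) rose as Mettl3 fell. Readers and erasers rose in 3 of 14, including Ythdc1, the nuclear reader (0.64 ± 0.08). Among 21 2-cell stage genes 0 rose and 1 fell (0 adjusted over the list alone, median 0.02). Naive pluripotency genes split into 9 rises and 7 falls (9 and 8 adjusted over the list alone, median -0.02, mean and test on the other side). Klf2, a naive-state factor (0.88 ± 0.08), and Dppa3 (1.71 ± 0.16) rose and Klf5 (-0.99 ± 0.07) fell. Mesoderm and endoderm genes gave 1 rise and 3 falls of 7 (median -0.64). T (-4.78 ± 0.65), Cxcr4 (-1.84 ± 0.38) and Eomes, a T-box factor (-1.15 ± 0.18), fell and Gsc (1.89 ± 0.25) rose. Trophoblast genes gave 3 and 2 of 8, Cdx2 again down (-4.54 ± 0.73). Neural genes gave 3 and 2 of 9, the neuronal tubulin Tubb3 (1.32 ± 0.14), Map2 (1.73 ± 0.30) and the progenitor filament Nes (1.53 ± 0.31) rising. Ribosomal protein genes fell in 14 and rose in 2 of 73 (11 and 1 adjusted over the list alone, median -0.08). The remaining lists gave, as rises and falls, 2 and 3 of 18 for deadenylation (Cnot3, -0.68 ± 0.10, Tob1, an antiproliferative adaptor, 0.52 ± 0.10) and 0 and 2 of 16 for decapping (Dcp2, the decapping enzyme, -0.39 ± 0.10, 1 fall over the list alone). They gave 1 and 1 of 10 for interferon and 3 and 4 of 14 for immediate-early (Jund, 1.10 ± 0.11, Myc, -2.57 ± 0.35, 4 and 4 over the list alone). Counts were 1 and 4 of 14 for formative (Lefty1, -2.02 ± 0.29), 0 and 2 of 6 for primitive endoderm, 2 and 1 of 4 for feeder genes and 2 and 1 of 15 for germline (Sycp3, -0.87 ± 0.14). Median and mean also differed in sign for decapping, immediate-early, formative and trophoblast genes. DESeq2 called 1241 genes (595 up, 646 down), without Zc3h13 and Dcp2. The edgeR count was 2319 without Mettl3 knockout library B.

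**Figure D1:**
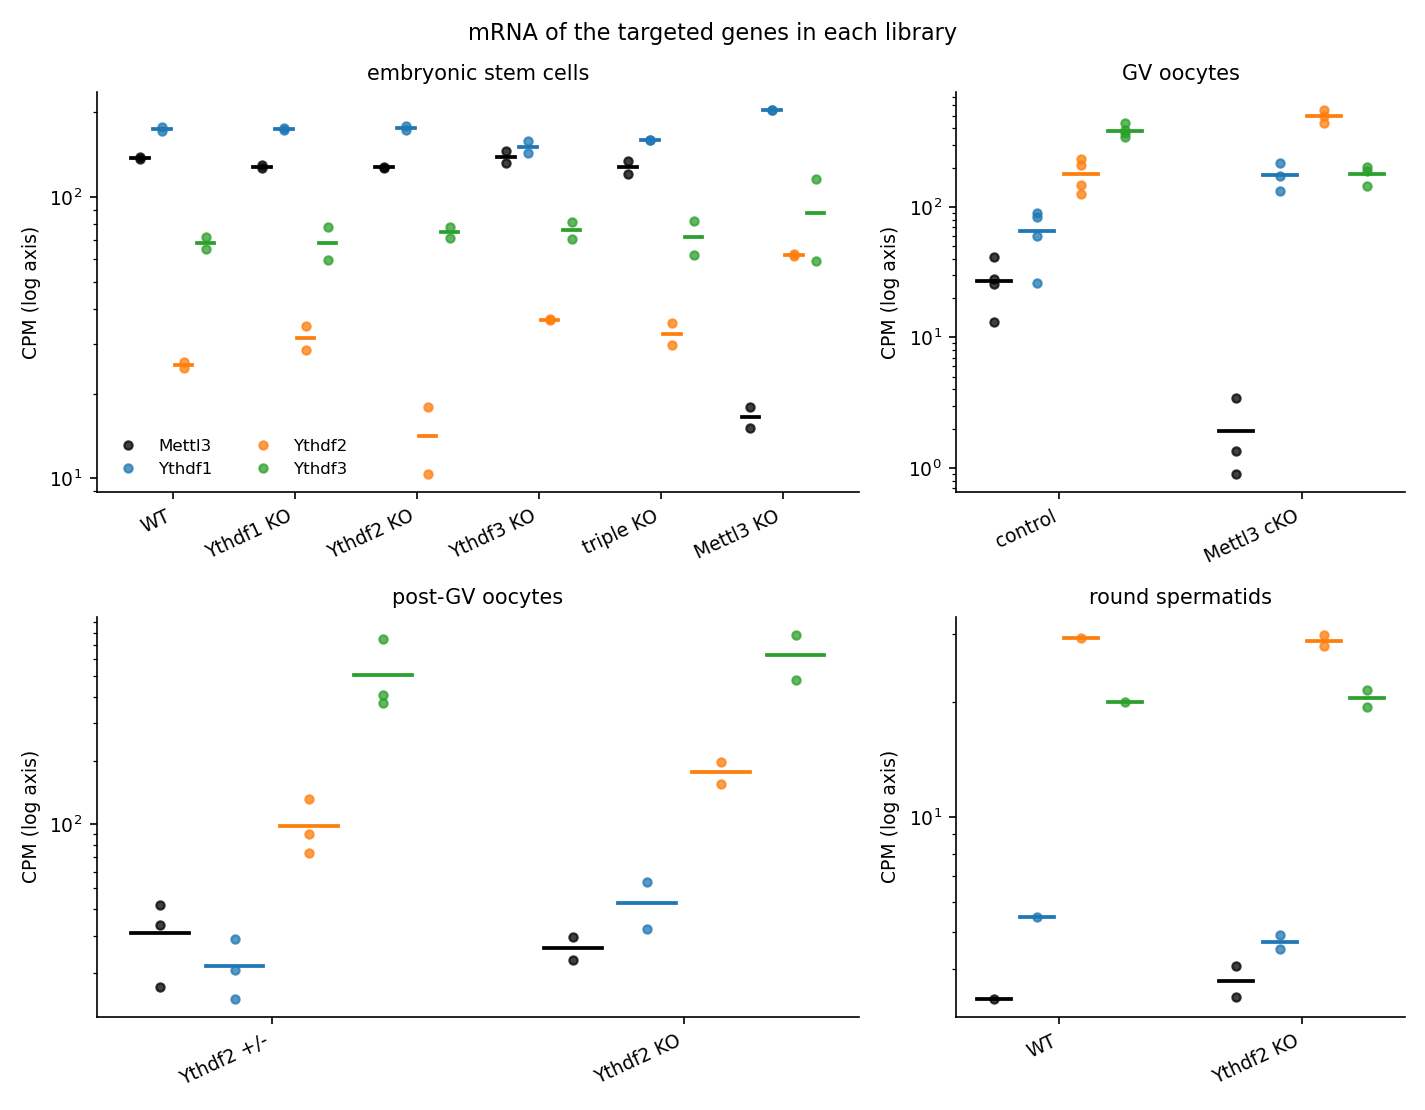
CPM of Ythdf1, Ythdf2, Ythdf3 and Mettl3 (log axis) in each of the 27 libraries by group; every point is 1 library and bars are group means.

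Set against each other directly, triple knockout cells held more of the 2-cell and p53 programmes than Mettl3 knockout cells. Adcy2 was at least 20.7-fold and Hoxa5 at least 6.47-fold higher, since Mettl3 knockout cells had 0 counts of either. Tcstv1 (5.54 ± 0.43), Pramel7 (5.09 ± 0.35) and Serpina3m, a serine protease inhibitor (5.17 ± 0.65), were higher too. Zbp1 (-3.99 ± 0.37), Grin1 (-3.21 ± 0.26), Lnx1, an E3 ligase of the Numb pathway (-3.13 ± 0.49), and Nkx6-3 (-3.04 ± 0.38) were lower. Mettl3 was higher in the triple knockout (2.96 ± 0.19, adjusted p = 5.80e-21) and Ythdf2 (-0.94 ± 0.21, adjusted p = 0.00263) and Ythdf1 (-0.35 ± 0.10, adjusted p = 0.0363) lower, with Ythdf3 not called (-0.21 ± 0.24).

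Calls reached 2271, 1255 higher and 1016 lower in the triple knockout. All 21 2-cell stage genes were higher (21 adjusted over the list alone, median 4.34, list adjusted p = 1.61e-57, adjusted p = 0.00303 with an estimated correlation). So were 10 of 17 p53 targets (11 adjusted over the list alone, median 0.66, adjusted p = 5.87e-07, adjusted p = 0.0109 with an estimated correlation), such as Phlda3 (1.11 ± 0.15) and Plk2 (1.06 ± 0.13). Of 15 germline genes 10 were higher (10 adjusted over the list alone, median 0.91, adjusted p = 7.2e-09, adjusted p = 0.0121 with an estimated correlation), such as Dazl (1.71 ± 0.12) and the X-linked homeobox gene Rhox13 (2.46 ± 0.33). ATF4 targets were lower in 7 and higher in 1 of 16 (8 and 2 adjusted over the list alone, median -0.39, adjusted p = 0.000219, lost at adjusted p = 0.069 with an estimated correlation). Trib3 differed by -1.90 ± 0.16 and Chac1 by -1.75 ± 0.21. Interferon-stimulated genes were lower in 4 of 10 (median -0.52, adjusted p = 0.0289, lost at adjusted p = 0.127 with an estimated correlation and also without Mettl3 knockout library B), including Ddx58 (-1.93 ± 0.49). Ribosomal protein genes were higher in 11 and lower in 1 of 73 (10 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.00134, lost at adjusted p = 0.326 with an estimated correlation).

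As higher and lower counts, the lists without a call as a whole gave 9 and 4 for naive pluripotency (Dppa2, 1.30 ± 0.11, Utf1, 0.99 ± 0.14) and 1 and 2 for writers (Wtap, -1.14 ± 0.10, Rbm15, -0.89 ± 0.12). They gave 0 and 3 for readers and erasers (Ythdc1, -0.56 ± 0.09), 2 and 2 for deadenylation, 1 and 0 for decapping, 1 and 4 for immediate-early and 2 and 1 for formative genes, the decapping and formative medians and means differing in sign. Counts were 1 and 0 for mesoderm and endoderm, 0 and 4 for neural (Map2, -3.06 ± 0.43), 3 and 0 for primitive endoderm, 3 and 1 for trophoblast and 1 and 0 for feeder genes. Over each list alone, naive pluripotency gave 10 and 6, decapping 0, immediate-early 2 and 5, formative 3 and 4, neural 1 and 4 and feeder genes 1 and 1. By fry, neural (adjusted p = 0.0015), primitive endoderm (0.00388), reader and eraser (0.0175) and naive pluripotency (0.0254) lists passed 0.05. So did mesoderm and endoderm (0.0288), immediate-early (0.0321) and feeder genes (0.0362), and the rest of these lists did not. DESeq2 called 678 genes, without Ythdf1, Ythdf2 and Ddx58. Here edgeR called 1403 without triple knockout library B and 1352 without Mettl3 knockout library B.

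Called 2-cell genes rose less in the triple knockout than the 3 single changes added together. The shortfall was -4.41 ± 0.77 for Tcstv1, -2.88 ± 0.54 for Usp17lb and -2.80 ± 0.48 for Usp17lc on the log2 scale. Calb2, the calcium buffer calretinin (-2.83 ± 0.37), and Pdzrn4 (-4.10 ± 0.84) also lay below the sum. Foxd1 (3.69 ± 0.71), Cd4, a T-cell surface gene (3.72 ± 0.65), Peg12, an imprinted gene (3.26 ± 0.50), and Myc (2.23 ± 0.57) lay above the sum of the singles. Ythdf1 (0.08 ± 0.19), Ythdf2 (0.35 ± 0.50), Ythdf3 (-0.20 ± 0.45) and Mettl3 (0.10 ± 0.21) did not depart from it by the test.

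Departures were called for 225 genes, 101 above and 124 below. The 2-cell list lay below in 5 of 21 (10 adjusted over the list alone, 0 positive, median -2.24, list adjusted p = 1.75e-11, adjusted p = 0.0131 with an estimated correlation). Naive pluripotency genes lay below in 4 of 26 (7 adjusted over the list alone, median -0.31, adjusted p = 4.4e-05, lost at adjusted p = 0.0938 with an estimated correlation). The called ones were Dppa5a (-0.77 ± 0.13), Tdh (-0.65 ± 0.13), Fbxo15 (-0.68 ± 0.15) and Dppa3 (-1.496 ± 0.33). The p53 list leaned below with 0 calls (median -0.25, adjusted p = 0.00871, lost at adjusted p = 0.0938 with an estimated correlation). Ribosomal protein genes had 1 below, Rps2 (-0.64 ± 0.15, median -0.14, adjusted p = 0.000364, lost at adjusted p = 0.359 with an estimated correlation). Formative genes had 2 above, Lefty1 (2.38 ± 0.48) and Lefty2 (0.90 ± 0.21), and 1 below, Otx2 (-2.25 ± 0.48). Germline genes had 1 below, Dpep3 (-1.92 ± 0.41), with the list median at 0.14 and the test direction below (2 below over the list alone). Single genes lay above in the ATF4, immediate-early and feeder lists (2 above and 1 below over the list alone for immediate-early, 2 above for feeder genes), and 1 below in primitive endoderm (1 and 1 over the list alone). Mesoderm and endoderm and trophoblast genes had 1 above each over the list alone and 0 calls. Of the other lists, median and mean or test differed in sign for readers and erasers, immediate-early genes and primitive endoderm. The contrast takes the wild-type pair 2 times, and DESeq2 called 5 genes, of those given values here Calb2 alone. With edgeR the count was 83 without wild-type library A, 103 without B and 127 without triple knockout library B.

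Mest was followed across the lines after its values were seen. It was called in the Ythdf2, triple and Mettl3 knockouts (72.1, 38.9 and 72.2 CPM) and not in the Ythdf1 (5.45 CPM) or Ythdf3 (3.46 CPM) knockouts, against 2.66 CPM in wild type.

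**Figure D2:**
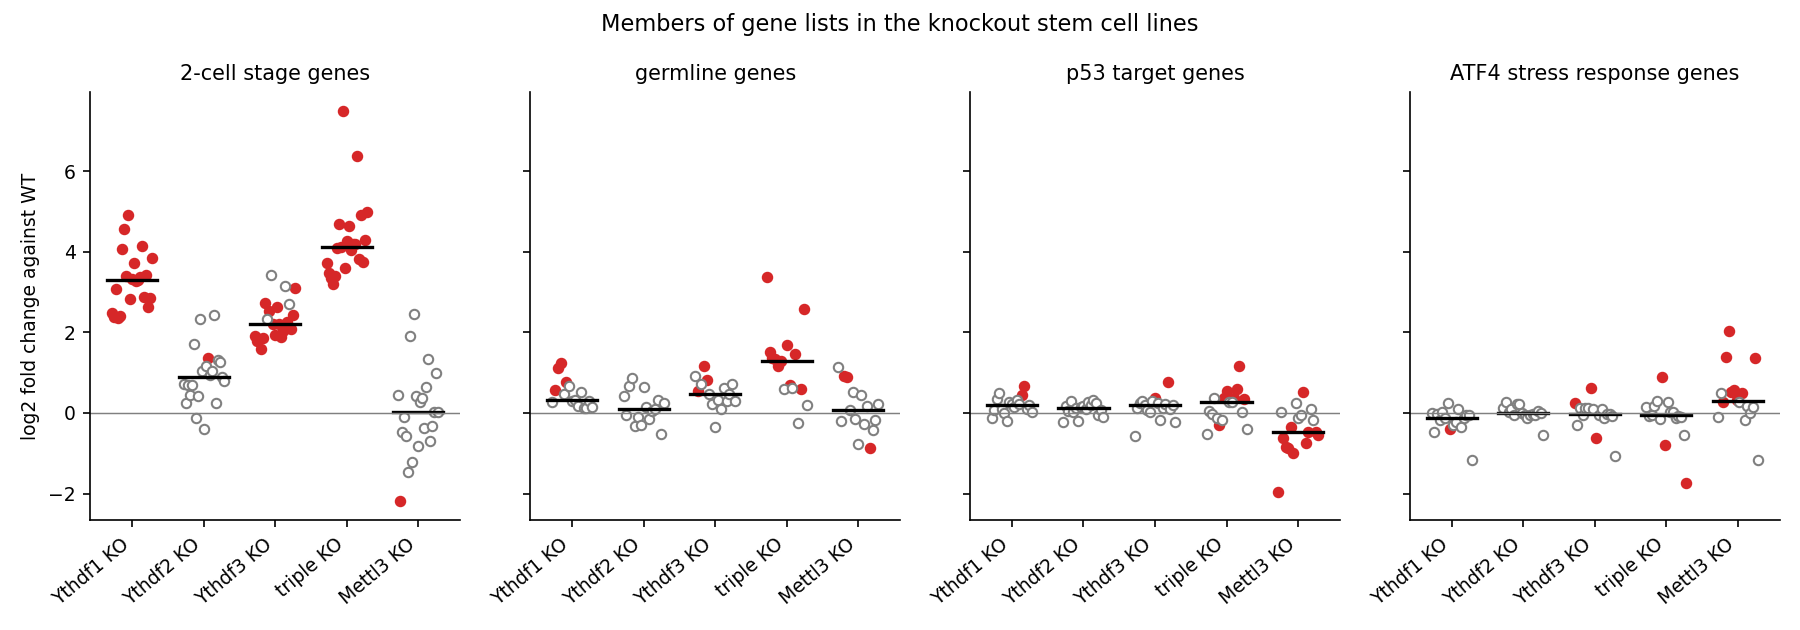
Log2 fold change against wild type of each tested member of the 2-cell, germline, p53 and ATF4 lists in the 5 knockout stem cell lines; points are genes, red where the adjusted p is under 0.05 and open grey otherwise, and bars are list medians.

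Many calls were shared between the knockouts, all set against the same wild-type pair. Unchanged groups sharing that pair had 0 to 0.15 calls in common each way on average in 20 simulated draws. Without changed genes such groups have few calls to share. The draws therefore cannot show how much the shared pair adds to overlaps between changed lines. The Ythdf1 and triple knockouts shared 200 rises and 141 falls where independent calls would share 31.0 and 21.1, with 3 genes in opposite directions. The Ythdf3 and triple knockouts shared 160 and 98 (27.6 and 15.6 if independent). Ythdf2, with fewer calls, shared 68 and 87 with the triple (13.3 and 15.0 if independent). Opposite genes numbered 1 and 4 in these pairs. Between singles, Ythdf1 and Ythdf3 shared 97 rises and 51 falls (4.06 and 1.98 if independent), Ythdf1 and Ythdf2 38 and 50 (1.95 and 1.90), and Ythdf2 and Ythdf3 37 and 38 (1.74 and 1.40), with 0 opposite in each. Triple and Mettl3 knockouts shared 703 rises and 750 falls (242 and 213 if independent) and 90 genes moved oppositely (455 if independent). The Mettl3 knockout shared 90 and 126 with Ythdf1 (35.5 and 27.1 if independent), 61 and 103 with Ythdf2 (15.2 and 19.2) and 95 and 84 with Ythdf3 (31.7 and 19.98). Opposite genes there numbered 21, 9 and 20 (62.5, 34.5 and 51.6 if independent). Of the 2997 triple knockout calls 2465 were in no single knockout, and 571 rises and 578 falls joined triple and Mettl3 knockouts alone. The single knockouts had far fewer calls (412, 227 and 340), so lack of a call there does not show lack of change. Tested directly, 225 genes departed from the sum of the singles.

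Genes called in all 5 lines, listed after their values were seen, were 19 up, such as Fbxo15, Rhox5, an X-linked homeobox gene, Apela, a peptide hormone of early embryos, and Chaf1b, a chromatin assembly subunit. Another 22 were down, such as Zmat4, Foxd1, Cdx2, Lgals1, a galectin, and Trh, a hormone precursor. Fold changes correlated at 0.715 between Ythdf1 and triple knockouts, 0.602 between Ythdf3 and triple and 0.471 between Ythdf2 and triple, where unchanged groups sharing the wild-type pair gave 0.412, 0.378 and 0.398 in 20 simulated draws. Triple and Mettl3 knockouts correlated at 0.476 (0.385 simulated), and the singles with Mettl3 at 0.324, 0.390 and 0.290, below the simulated 0.423, 0.407 and 0.389 (0.234, 0.252 and 0.195 when each side had its own wild-type library). Their covariance stayed above the simulated one by 0.0894, 0.0891 and 0.0721. The simulated groups held no changed genes, and changed genes alter the spread that enters a correlation. A correlation above or below the simulated one thus cannot show how much lines share. Among singles, correlations were 0.580, 0.690 and 0.564 (0.433, 0.414 and 0.394 simulated) for Ythdf1 with Ythdf2, Ythdf1 with Ythdf3 and Ythdf2 with Ythdf3. With library A of 1 line against wild-type library A, and library B of the other line against wild-type library B, all 10 pairs correlated above 0. Ythdf1, Ythdf2 and Ythdf3 with the triple knockout gave 0.518, 0.270 and 0.408, triple with Mettl3 0.421, and the singles 0.330, 0.428 and 0.255 in the order above. These values carry no count noise of a shared library, but a departure of the wild-type line itself would enter both sides. The overlaps of calls used the shared pair.

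In GV oocytes without Mettl3, the Mettl3 transcript fell (log2 change -3.77 ± 0.57, adjusted p = 0.00182, 1.90 ± 1.37 against 27.2 ± 11.6 CPM, 3 and 4 libraries). Ythdf2 (1.48 ± 0.24, 497 ± 56.1 against 179 ± 50.8 CPM) and Ythdf1 (1.43 ± 0.38, 174 ± 42.1 against 64.8 ± 28.8 CPM) rose and Ythdf3 fell (-1.11 ± 0.20, 178 ± 30.5 against 385 ± 42.1 CPM). Sohlh1, a transcription factor of early follicle oocytes, rose most among the named genes (7.56 ± 0.41, 189-fold, adjusted p = 4.16e-05, 87.3 ± 18.9 against 0.427 ± 0.238 CPM), with the heat-shock gene Hspa1a (7.51 ± 0.65), Corin, a membrane protease (6.02 ± 0.33), and Shisa2, a signalling inhibitor (5.65 ± 0.41). Ldha, lactate dehydrogenase (-5.26 ± 1.14), Npr2, the natriuretic peptide receptor of cumulus cells (-5.19 ± 1.19), Tac2, a tachykinin (-5.13 ± 0.64), and Inhbb, an inhibin subunit (-5.11 ± 1.53), had large falls, that of Inhbb lost without the expression filter.

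Calls covered 28.8% of 13551 tested genes, 3907 in number (2092 up, 1815 down, 1692 and 1504 past 2-fold). Granulosa cell markers, which belong to the follicle's somatic cells, fell in 11 of 20 (13 falls adjusted over the list alone, median -3.19, list adjusted p = 0.000492, lost at adjusted p = 0.941 with an estimated correlation). Among them were the aromatase gene Cyp19a1 (-3.57 ± 0.33, adjusted p = 2.51e-04, 3.46 ± 1.33 against 42.0 ± 5.06 CPM), Slc38a3, an amino acid transporter (-4.29 ± 1.00), and Inhba (-3.76 ± 0.97). Mean log2 CPM of these markers differed between libraries, at 3.54, 5.26, 6.58 and 3.75 in the controls and -0.40, 2.45 and 0.73 in the knockouts.

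**Figure D3:**
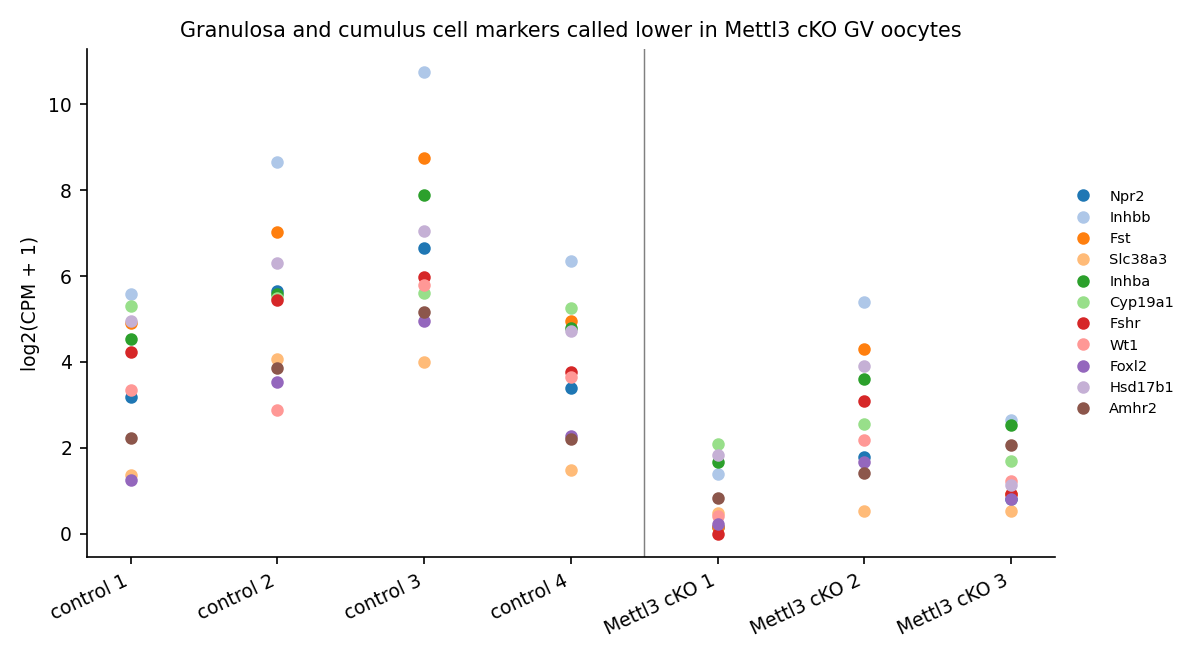
Level, as log2 of CPM plus 1, of the 11 granulosa cell markers called in GV oocytes, by library; each point is 1 marker in 1 library.

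Other lists were divided, with no call as a whole. Maternal-effect genes rose in 7 and fell in 8 of 33 (8 and 9 adjusted over the list alone, median 0.24). Dppa3 rose (1.22 ± 0.20), and Rfpl4, an oocyte RING protein (-2.09 ± 0.24, 407 ± 72.3 against 1738 ± 368 CPM), and the oocyte gene Oog3 (-1.24 ± 0.22) fell. Among 19 translation and storage genes 1 rose and 4 fell (1 and 7 adjusted over the list alone, median -0.04). Several mRNA decay genes fell, namely Btg4, the oocyte deadenylation adaptor (-1.65 ± 0.23, 793 ± 43.9 against 2494 ± 599 CPM), the deadenylase Cnot7 (-1.51 ± 0.22) and the decapping genes Dcp1a (-1.13 ± 0.19) and Dcp2 (-1.20 ± 0.32). Tob1 (1.47 ± 0.26) and Lsm1, of the decay-linked Lsm ring (1.13 ± 0.27), rose. Deadenylation gave 1 rise and 3 falls of 19 (1 and 2 over the list alone) and decapping 2 and 2 of 18. The writer list rose in 3 and fell in 1 of 9. The writer partners Cbll1 (2.00 ± 0.20, 250.0 ± 33.0 against 62.3 ± 8.66 CPM) and Rbm15 (1.04 ± 0.22) and the separate methyltransferase Mettl16 (0.87 ± 0.26) rose. Readers and erasers gave 2 and 2 of 13, with the eraser Alkbh5 down (-1.01 ± 0.21) and median and mean differing in sign.

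Among 15 p53 targets 5 rose (median 0.31), including Pmaip1 (3.75 ± 0.63), Aen (2.60 ± 0.77), the zinc-finger gene Zmat3 (1.49 ± 0.35) and Ccng1 (1.40 ± 0.33). ATF4 targets rose in 3 and fell in 1 of 18, Chac1 (3.40 ± 0.36) against Psat1 (-3.39 ± 1.04). The 2-cell list rose in 4 and fell in 1 of 10 (4 and 2 adjusted over the list alone, median 1.98), Usp17lc (5.44 ± 0.82) against Tcstv1 (-1.80 ± 0.30). Meiotic genes gave 5 rises and 3 falls of 30. Smc1b, a meiotic cohesin (1.64 ± 0.22), and Wee1, a mitotic inhibitor kinase (1.57 ± 0.28), rose. Aurkc, a meiotic kinase (-1.16 ± 0.24), and Fbxo43, a regulator of metaphase arrest (-1.01 ± 0.21), fell. Chromatin regulators gave 2 and 2 of 20 (median and mean differing in sign), the deacetylases Hdac1 (1.37 ± 0.27) and Sirt1 (1.004 ± 0.29) against the methylation genes Dnmt3l and Dnmt3a (for the latter -0.70 ± 0.22). Interferon genes gave 2 and 1 of 10 (Zbp1, 2.94 ± 0.76, Eif2ak2, -2.16 ± 0.72), immediate-early genes 2 and 2 of 16 (Ier2, 1.51 ± 0.34, Myc, -3.10 ± 0.90), and ribosomal protein genes 0 of 70 (median -0.26). DESeq2 called 4968 genes with more falls (2684) than rises (2284). By contrast edgeR called 2254 without knockout library 1, 2581 without knockout library 2 and 2425 without control library 2. In the fit without controls 2 and 3, added after the data were seen, 16 named genes lost their call. Another 53 kept their state and 1 gained a call.

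In post-GV oocytes the Ythdf2 transcript stood at 176 ± 29.4 against 98.5 ± 30.5 CPM (2 knockout and 3 heterozygous libraries), a change of 0.84 ± 0.40, adjusted p = 0.848 without a batch term and 0.84 ± 0.33, adjusted p = 0.211 with one. The comparison fixed in advance called 0 of 13910 genes by edgeR, with 782 at an unadjusted p under 0.05 and a smallest adjusted p of 0.512, while DESeq2 called 77 (67 up, 10 down). Values in the deposited batch-adjusted table part the libraries into 2 batches, knockout 1 with heterozygotes 1 and 2, and knockout 2 with heterozygote 3. A batch term, chosen after seeing the data, gave 258 calls (192 up, 66 down). The values that follow are from that fit.

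Mos, the kinase that holds eggs at metaphase, rose by 4.501 ± 0.39, 22.6-fold, adjusted p = 5.81e-05 (771 ± 156 against 35.5 ± 17.2 CPM), and Lbr, the lamin B receptor, by 3.44 ± 0.31 (576 ± 55.9 against 51.8 ± 6.75 CPM). Plat, tissue plasminogen activator and a stored maternal mRNA (3.30 ± 0.43), Rbm44, a germ-cell RNA-binding gene (3.42 ± 0.43), and the E3 ligase gene March7 (3.53 ± 0.35) rose as well. The largest rise among the named genes, of the secreted immune gene Retnla (8.59 ± 0.68), varied widely (49.8 ± 55.6 against 0.102 ± 0.176 CPM). Mgp, a matrix calcification inhibitor (-4.19 ± 0.87), Enpp1, a nucleotide pyrophosphatase (-3.40 ± 0.53), Fabp7, a fatty acid carrier (-2.95 ± 0.64), and the keratin Krt18 (-2.87 ± 0.56) fell. Ythdf1 (1.02 ± 0.46), Ythdf3 (0.20 ± 0.30) and Mettl3 (-0.24 ± 0.44) were not called.

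Immediate-early genes fell in 5 of 20 (13 adjusted over the list alone, median -1.62, list adjusted p = 1.27e-10, lost at adjusted p = 0.773 with an estimated correlation). The falls include the growth-factor-induced factors Egr2 (-2.88 ± 0.53) and Jun (-2.33 ± 0.53), the phosphatase Dusp6 (-2.10 ± 0.40) and the antiproliferative gene Btg2 (-1.86 ± 0.42). Granulosa cell markers fell in 1 of 21, Fst, the activin-binding follistatin (-3.33 ± 0.61), with 1 rise and 6 falls adjusted over the list alone (median -1.08, adjusted p = 0.000137, lost at adjusted p = 0.773 with an estimated correlation). Whether somatic RNA carried in the heterozygous libraries adds to the falls in this experiment was not tested. Ribosomal protein genes leaned down with 0 calls of 70 (median -0.48, adjusted p = 0.000137, lost at adjusted p = 0.785 with an estimated correlation). Maternal-effect genes rose in 2 of 31, Astl, the oocyte protease ovastacin (2.32 ± 0.46), and Khdc3, of the subcortical maternal complex (2.23 ± 0.50). With 7 adjusted over the list alone, the list leaned up (median 0.28, adjusted p = 0.00103, lost at adjusted p = 0.785 with an estimated correlation). Meiotic genes rose in 2 of 30, Mos and the checkpoint kinase Bub1b (1.94 ± 0.36, 2 adjusted over the list alone, median 0.18, adjusted p = 0.0164, lost at adjusted p = 0.785 with an estimated correlation). Chromatin regulators rose in 1 of 20, Sirt1 (2.18 ± 0.36, 3 adjusted over the list alone, median 0.22, adjusted p = 0.0164, lost at adjusted p = 0.785 with an estimated correlation).

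Without the batch term these lists had 0 called genes (1 meiotic and 1 chromatin rise over the list alone). As a whole the same 6 were called in the same directions, immediate-early (median -1.72, adjusted p = 1.12e-05), ribosomal (-0.89, 0.000104), maternal-effect (0.31, 0.000154), granulosa (-1.66, 0.00321), meiotic (0.18, 0.00741) and chromatin (0.28, 0.00779), each lost at adjusted p = 0.751 with an estimated correlation. Without knockout 2 all 6 of these list calls ended, the ribosomal one at adjusted p = 0.870 with the test direction up. Without heterozygote 2 all but the immediate-early one ended (ribosomal 0.571). With the term, the ribosomal, maternal-effect, meiotic and chromatin lists lost their calls without knockout 1 and without heterozygote 2, and the chromatin list also without knockout 2 and without heterozygote 3. With the term, deadenylation and p53 lists had 1 fall each of 19 and 17. The writer (median 0.25), reader and eraser (0.24, 2 rises over the list alone), decapping (-0.03, 1 rise over the list alone), interferon (0.05), ATF4 (-0.07, 2 rises over the list alone), 2-cell (0.50, 3 of 6 over the list alone) and translation and storage (-0.09, 1 rise over the list alone) lists had none. Median and mean or test differed in sign for deadenylation, decapping, ATF4 and translation and storage. This fit called 845 without knockout 1, 623 without knockout 2, and 98, 68 and 496 without heterozygotes 1, 2 and 3. DESeq2 with the term called 714 (362 up, 352 down), and the first batch alone gave 666 (516 up, 150 down). Under RLE scaling Mgp, Fabp7, Jun, Btg2, Astl and Khdc3 lost their calls.

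In round spermatids Ythdf2 stood at 28.9 ± 1.40 against 29.2 CPM (-0.02 ± 0.33, adjusted p = 0.992), with Ythdf1 (-0.21 ± 0.52), Ythdf3 (0.04 ± 0.36) and Mettl3 (0.15 ± 0.59) not called. Zmynd8, a chromatin reader, rose by 5.31 ± 0.50, 39.7-fold, adjusted p = 1.71e-15 (30.6 ± 0.780 against 0.767 CPM, 2 knockout libraries and 1 wild-type library). The unconventional myosins Myo7a (4.19 ± 0.49) and Myo1e (3.11 ± 0.42) and the noncoding RNA Gas5 (3.34 ± 0.42) rose. Ptchd3, a sperm-specific patched-domain gene (-3.03 ± 0.27, adjusted p = 1.84e-17, 21.1 ± 2.54 against 173 CPM), Chuk, the kinase IKK alpha (-2.63 ± 0.35), and Mrto4, a ribosome assembly gene (-2.60 ± 0.31), fell.

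Calls numbered 785 of 16031 genes (361 up, 424 down, 316 and 299 past 2-fold). Round spermatid and spermiogenesis genes rose in 3 of 39 (7 rises and 1 fall adjusted over the list alone, 31 positive, median 0.37, list adjusted p = 0.0121, lost at adjusted p = 0.97 with an estimated correlation). The linker histones Hils1 (0.90 ± 0.25) and H1fnt (0.79 ± 0.24) and the transition protein Tnp1 (0.78 ± 0.24, 1084 ± 45.9 against 633 CPM) were called. Spermatocyte genes fell in 3 of 28 (4 adjusted over the list alone, median -0.32, adjusted p = 0.00519, lost at adjusted p = 0.97 with an estimated correlation). The meiotic factor Mybl1 (-1.07 ± 0.25), the cyclin Ccna1 (-1.01 ± 0.25) and Piwil1, a piRNA-binding protein (-1.11 ± 0.30), fell. Single falls came from the writer (Mettl14, the partner of Mettl3, -1.41 ± 0.37), deadenylase (Cnot4, -0.85 ± 0.26), decapping (Edc4, -1.23 ± 0.31) and ribosomal (Rpl4, -0.84 ± 0.24) lists. Interferon genes split 1 and 1 of 11 (Ddx58, 1.65 ± 0.49, Stat2, -1.26 ± 0.39, 1 and 2 over the list alone). The p53 targets rose in 2 of 14, Ccng1 (1.75 ± 0.49) and the death receptor Fas, absent in wild type and at least 12.8-fold higher. Reader and eraser, ATF4, 2-cell and immediate-early lists held 0 calls. Median and mean or test differed in sign for the writer, reader, interferon, p53 and immediate-early lists. Markers of spermatogonia, Sertoli, Leydig and blood cells also held 0 calls, with medians of 0.55, 0.70, 0.47 and 1.06 (1 rise each for spermatogonia and blood over the list alone). With 1 wild-type library the model has 1 residual degree of freedom and assumes that library varies like the knockout pair. DESeq2 called 398 genes, without H1fnt, Tnp1, Piwil1, Mettl14, Cnot4, Rpl4, Ddx58, Stat2 and Ccng1, and the 5 CPM filter also ended the calls of Mybl1 and Edc4.

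Across experiments no libraries are shared. Loss of Mettl3 moved 353 genes up and 207 down in both stem cells and GV oocytes, where independent calls would give 253 and 141, and 352 genes oppositely (385 if independent), with fold changes correlated at 0.0883 over 10295 genes. Triple knockout stem cells and Mettl3-null GV oocytes shared 297 rises and 160 falls (215 and 108 if independent, correlation 0.0989). For post-GV oocytes the values here use the batch term, chosen after seeing the data. GV oocytes without Mettl3 and post-GV oocytes without Ythdf2 shared 49 rises and 22 falls (25.4 and 6.36 if independent, correlation 0.235), the falls including the granulosa marker Fst. Without the term 0 were shared, with a correlation of 0.194. Granulosa cell markers leaned down in both experiments (medians -3.19 and, with the term, -1.08). More carried somatic RNA in both sets of controls could thus add to the shared falls and the correlation, which was not tested. Ythdf2 loss gave few shared calls between tissues. Stem cells and post-GV oocytes shared 3 rises and 0 falls (1.05 and 0.315 if independent). Stem cells and spermatids shared 1 and 3 (1.01 and 3.34), and post-GV oocytes and spermatids 1 and 1 (2.18 and 1.35). Few genes were there to share, with 177 called in stem cells and 170 in post-GV oocytes among those tested in both. Post-GV controls were heterozygous and the others wild type. Low overlap here thus does not show that tissues respond differently.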

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

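The comparison of groups and experiments was set before the results, but its post-GV values use the batch term, chosen after the data were seen. Without that term edgeR called 0 genes there (782 at an unadjusted p under 0.05, and 77 by DESeq2), so 0 were opposite. The tests of single libraries covered 70 named genes in the 4 GV control libraries, and groups of 3 or fewer were not tested. By that test chance alone picks about 1 in 20 genes, and 3 were picked. Inhba, an inhibin subunit of granulosa cells, stood at 235 CPM in control library 3 against 22.2 to 46.8 CPM in the others, the library that also held the most granulosa RNA by its markers. Aldh1l2, a mitochondrial folate enzyme, stood at 3.878 CPM in control library 3 against 1.31 to 1.59 CPM. Gm5662, a 2-cell stage transcript, had 0.06934 CPM in control library 1 and 0 in the others. That is about 1 read among the 15133294 counts of that library. Any gene seen in 1 control library alone is picked by this test.

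Some genes were called in opposite directions on loss of the same gene in different cells, in numbers near those of independent calls. With Mettl3 removed, 352 genes called in both stem cells and GV oocytes moved oppositely, where 385 would if the calls were independent. With Ythdf2 removed the numbers were 2 between stem cells and post-GV oocytes, 3 between stem cells and spermatids and 4 between post-GV oocytes and spermatids, where 1.49, 3.79 and 5.18 would. Among the readers, Ythdf1 changed less in Mettl3-null stem cells than in GV oocytes by -1.21 ± 0.39 on the log2 scale (adjusted p = 0.0086), and Ythdf3, which fell in GV oocytes, differed by 1.38 ± 0.30 (adjusted p = 3.69e-05). Ythdf2 differed by -1.69 ± 0.44 between its own knockouts in stem cells and post-GV oocytes (adjusted p = 0.00581). These p-values are from a normal z test that ignores how few libraries the oocyte fits hold, so they may be too small. Neither Ythdf2 change was called on its own, and the reference was wild type in stem cells and heterozygous in oocytes. Stem cells and oocytes were made into libraries by different protocols, and a different part of the gene deleted in each line would give such a gap too; neither was tested.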

How the results depend on the processing

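Where called in the main fit or the alternative, named genes and lists held their direction in every alternative run for them but 1. Lists were not run under DESeq2, and direction was not compared for those called in neither fit. Counts moved most with the tool and with single libraries, or in post-GV oocytes with the batch. The balance of rises and falls was less stable. In GV oocytes 2092 up and 1815 down became 1861 and 2106 with RLE scaling, 2284 and 2684 with DESeq2, 1289 and 1292 without knockout 2, 1626 and 1663 without knockout 3, and 1594 and 1667 without controls 2 and 3. In spermatids 361 and 424 became 182 and 159 with the 5 CPM filter and 200 and 198 with DESeq2. In post-GV oocytes with the batch term 192 and 66 became 407 and 438 without knockout 1 and 45 and 53 without heterozygote 1. In Mettl3-null stem cells 1820 and 1809 turned with DESeq2 (595 and 646), both filters (1944 and 1978 without one, 1930 and 1951 at 5 CPM), without wild-type A (1371 and 1447) and without knockout B (1128 and 1191), and for Ythdf2 100 and 127 turned to 30 and 24 without knockout B. DESeq2 called 56 genes for Ythdf1, 11 for Ythdf2, 29 for Ythdf3, 785 for the triple knockout, 1241 for Mettl3, 678 for triple against Mettl3 and 5 beyond the sum; it called 77 in post-GV oocytes (714 with the batch term) and 398 in spermatids. No named gene called in either fit turned direction under DESeq2, while 178 lost their call and 697 kept their state. Over the fits that left out 1 library, 467 named-gene values lost their call and 3551 kept their state. The 5 CPM filter gave 341 calls in spermatids, and with the batch term in post-GV oocytes RLE scaling gave 108, no filter 452 and the 5 CPM filter 150; without that term 0 became 258 with it and 666 in the first batch alone. Leaving out 1 library gave 192 to 240 calls for Ythdf1, 54 to 122 for Ythdf2, 112 to 199 for Ythdf3, 1796 to 2239 for the triple, 2319 to 2818 for Mettl3, 1352 to 1670 for triple against Mettl3, 83 to 199 beyond the sum, 2254 to 4243 in GV oocytes, 0 to 1 in post-GV oocytes (1 without knockout 1) and 68 to 845 there with the batch term; spermatids leave no residual degree of freedom for this. With replicate number as a block, calls were 420, 241, 348, 3006, 3630, 2273 and 225 in the stem cell contrasts in that order, 4540 in GV oocytes (2357 up, 2183 down) and 3 in post-GV oocytes. Lists called as a whole went from 39 to 10 of 172 with an estimated correlation, and the 1 reversal was the ribosomal protein list in post-GV oocytes without knockout 2, up at an adjusted p of 0.870 (3.26e-12 without heterozygote 3, the lowest). At an adjusted p under 0.01, same-direction overlaps were 36 (Ythdf1 and Ythdf2), 74 (Ythdf1 and Ythdf3), 200 (Ythdf1 and triple), 102 (Ythdf1 and Mettl3), 34 (Ythdf2 and Ythdf3), 65 (Ythdf2 and triple), 84 (Ythdf2 and Mettl3), 119 (Ythdf3 and triple), 76 (Ythdf3 and Mettl3), 829 (triple and Mettl3), 196 (Mettl3 in stem cells and GV oocytes), 9 (GV and post-GV oocytes), 1 and 1 (Ythdf2 in stem cells with post-GV oocytes and with spermatids) and 0 (post-GV oocytes and spermatids). Over genes with a mean log2 CPM of at least 4, correlations were 0.342 (Ythdf1 and Mettl3), 0.509 (Ythdf2 and triple), 0.427 (Ythdf2 and Mettl3), 0.630 (Ythdf3 and triple), 0.313 (Ythdf3 and Mettl3) and 0.509 (triple and Mettl3). Simulated unchanged groups gave 0.424, 0.399, 0.411, 0.382, 0.387 and 0.390 over these genes. Ythdf2 with Mettl3 lay above its simulated value here and below it over all genes. Neither decides what is shared, since the simulated groups held no changed genes. RLE scaling, no filter, the 5 CPM filter and the compared groups alone left every other count within 1.5 times.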

Other observations

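The tests by motif, of the GV grouping and of all called falls were set before their results, but the last and the post-GV motif test use fits added after the data were seen. The tests of marker correlation, of the 2-cell genes and of batch were chosen after seeing the results.

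Granulosa cell markers fell in GV oocytes without Mettl3, and 2 control libraries held most of that RNA. If somatic RNA carried in some libraries were the cause, the 11 called markers would move together across the 4 control libraries. The median correlation between pairs of them was 0.952 (lowest 0.352), so carried somatic RNA is a likely cause of part of the fall. Cyp19a1 is an exception, at 37.4 to 48.0 CPM in the 4 controls and 2.25 to 4.88 CPM in the knockouts, and its log2 change of -3.57 was -3.54 without controls 2 and 3, so its fall does not follow the carried RNA. Without controls 2 and 3 their median log2 change went from -3.57 to -2.25 and 4 stayed called. The median of all called falls went from -1.78 to -1.77, with 0.995 of the fall kept. This refit cannot decide whether carried RNA made all of them, because controls 1 and 4 still held more marker RNA than the knockouts. Their mean log2 CPM was 3.54 and 3.75, against -0.40, 2.45 and 0.73. Of 1815 called falls, 908 were not higher in controls 2 and 3 than in 1 and 4, and 240 were over 2-fold higher. Those 908 were picked by that very difference, so they cannot show that carried RNA had no part in their falls. Of 1801 refitted falls 1369 stayed called with 0 changing sign. A count of granulosa cells left on the oocytes of each mouse would settle what remains.

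The 2-cell stage genes rose in the Ythdf1, Ythdf3 and triple knockouts and not in the Mettl3 knockout. In the Ythdf2 knockout 19 of 21 were positive (median 0.90, list adjusted p = 2.62e-06, lost at 0.0701 with an estimated correlation). Near-identical copies count as separate genes in these numbers, so the list counts and p-values rest on fewer independent genes than 21. Reads shared between near-identical copies are unlikely to make the rise, since Arg2, Tmem92 and Zfp352, which are not such copies, had a median of 3.72 in the triple knockout. A low level in the wild-type pair alone is unlikely too, as the median against the Mettl3 knockout was 4.34. Whether lines differ apart from the genotype could not be told, because the labels name 0 separately derived lines per genotype. The rise may come from loss of the readers, or from lines that hold more cells in a 2-cell-like state; rescue by reader expression, or counts of Zscan4-positive cells in more lines per genotype, would part these.

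If the mark acted mainly by speeding decay of the mRNAs that bear it, transcripts with more distal DRACH motifs (the sequence context of m6A) would rise on its loss. The rank correlation given length, exons and level, less that of unchanged libraries, was 0.00739 ± 0.0120 in Mettl3 and -0.0145 ± 0.0133 in triple knockout stem cells, -0.0416 ± 0.0129 in GV oocytes, 0.0293 ± 0.0109 in post-GV oocytes and 0.0151 ± 0.0127 in spermatids, each under the 0.05 set beforehand. The standard errors here come from resampling genes 200 times with the libraries held fixed, so they leave out spread between libraries. Before that subtraction the values were 0.0384, 0.0165, -0.0255, -0.000528 and 0.0188 in the same order, also under 0.05. Unchanged libraries gave 0.0311 in stem cells, 0.0162 and -0.0298 in GV and post-GV oocytes and 0.00367 in spermatids. Their sign depends on which library is taken from which. In the other order Mettl3 stem cells would pass 0.05, so the differences cannot decide for or against such a rise. The GV correlation was negative before the subtraction too. In post-GV oocytes the difference was positive and within 2 standard errors of 0.05, but only through the -0.0298 of the unchanged pair. The median log2 change there was -0.17 in genes with few motifs and 0.10 in genes with many, not adjusted for length, exons or level. Spermatids gave 0.0025 and 0.115, and Mettl3 stem cells -0.018 and -0.016. Triple knockout stem cells (0.036 and -0.088) and GV oocytes (0.086 and -0.082) ran the other way. A smaller rise stays open in post-GV oocytes. Motif number is a weak stand-in for methylation, so a map of m6A in these cells would be the stronger test.

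Chance was weighed against the GV calls by parting the 7 libraries in all 35 ways. The real grouping gave 3907 calls and 1 of 35 groupings reached that number; the highest other gave 0. If the libraries are taken as unpaired, chance can be excluded at that share. If their numbers pair them, as the block fit takes them, the real grouping is 1 of 8 that part the 3 pairs. The highest other of these gave 0 too, and 8 are too few for a share under 0.05. The rest hold both libraries of at least 1 pair in the same group, and each grouping but the real one mixes knockout with control libraries. In post-GV oocytes, the median squared log2 difference between heterozygous libraries was 3.59 times as large across the batches (0.347 and 0.900) as within (0.174). Both pairs across hold heterozygote 3, so a departure of that library alone could give this. Over all libraries, pairs across batches gave 0.347 to 1.04 and pairs within 0.0882 to 0.322, close but without overlap. A batch difference may be why 0 genes were called without a batch term, and no test parts it from single libraries.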
